A study of Homo sapiens with 31 samples.

How the data were processed

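Poly(A) RNA of H460 cells was sequenced 6 h after treatment in 31 libraries of 8 groups, with 4 libraries per group except Nutlin-3 with 3. Per the labels, each sample joined cells of 2 wells, RNA came from a Qiagen RNeasy Plus Micro kit and libraries from the TruSeq stranded mRNA kit. Per the submitters' processing notes, FastQC, Picard, SAMtools, STAR 2.4.0 and DESeq2 were used; the other versions, and whether counting used the strand, are not given in the sources used here. The notes name the build mm10, whereas the header of the table names hg19 and its genes are human, so positions are given on hg19. The deposited signal values are read counts per gene that the authors normalized per library before deposit, in 1 table of 74834 rows and 31 sample columns.

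Of the rows, 51656 have no gene symbol, 708 combine several genes, 335 hold a gene with small RNAs and 10 repeat a symbol. All 690132 values above 0 were whole multiples of 1 step per library (100% within 0.1 step, largest distance 0.00538 steps), so whole reads were recovered by division by that step. These gave 33.4 M to 82.5 M reads per library. Even numbers made up 55.8% to 59.2% of the recovered counts below 1000, so the unit of a read may be a read end, and count models were used as alternatives only.

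The 16259 rows with a mean normalized value of at least 10 were tested; 2416 of them have no symbol and 507 combine several genes. The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend) on log2(normalized value + 1), with all 31 samples in 1 fit by group and no replicate block (23 residual and 7.14 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all rows tested. There were 13 comparisons: B87, DMKG, B87+DMKG, Nutlin-3, Rita and both triple treatments against Control, each triple treatment against B87+DMKG, the triple treatments against each other, the combination against the sum of its parts, and the effect of each inhibitor with minus without B87+DMKG. Reversal was the share of genes changed by B87+DMKG that were called in the opposite direction when an inhibitor was added, with the B87+DMKG libraries split between the steps in 6 ways and 20 simulated draws of unchanged groups as a measure of the shared libraries.

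Gene lists covered p53 targets, glycolysis, hypoxia response, integrated stress response, aminoacyl-tRNA synthetases, endoplasmic reticulum genes, cholesterol, complex I, mitochondrially encoded proteins, the tricarboxylic acid cycle, mitosis, DNA replication, cell death, immediate early genes, heat shock, NRF2 targets, NF-kB, nucleolar genes, glucose-sensing genes, and fibroblast, leukocyte and endothelial markers. They were tested with camera of limma at a preset inter-gene correlation of 0.01 and again with the correlation estimated, with fry beside it, adjusted over the lists of a comparison. Of 22 lists 19 had enough tested members. Genes named in the text followed a rule set before the data were examined: per comparison the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 50 and groups that did not overlap (not required for contrasts of 4 groups), up to 4 called members per list with the largest change, and a fixed set of genes, among them those printed in every comparison (MDM2, CDKN1A, GDF15, HK2, SLC2A1, LDHA, VEGFA, CA9, DDIT3, ATF4, ASNS, TRIB3, TXNIP, BBC3 and PARP1). The genes printed are a selection from those the rule allows.

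Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, quantile normalization, the same total in every library, only the groups compared, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, 1 library left out, an absolute log2 fold change of at least 1, and the estimated correlation for lists. DESeq2 gave no adjusted p for 2 rows per comparison and 2523 in B87, which were kept as not available. After the data were seen, DMKG libraries 1 and 2 or 3 and 4 left out, and rows that name 1 gene only, were added. Gene span was the distance from start to end in the table, and exonic length came from GENCODE v29 by symbol for 97.5% of 13334 genes.

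The fits were tested on simulated data with the means of the Control libraries and the spread of the Control and B87 libraries. B87+DMKG libraries varied more (median SD of log2 values 0.249, against 0.136 in Control and 0.153 in B87). Recovery and errors in the real comparisons may therefore be worse than these figures. Only 67, 67 and 66 genes were changed by 1.5, 2 and 4-fold, against 9922 rows called in the real B87+DMKG vs Control. False calls can be more numerous among so many calls. The values given to limma were scaled by the true factors, so scaling under widespread change was not tested. For B87+DMKG vs Control limma recovered 67.2% of 1.5-fold, 79.1% of 2-fold and 93.9% of 4-fold changes, with 7 unchanged genes called (16259 rows tested, the changed ones included). edgeR recovered 67.2%, 80.6% and 95.5% with 7, and DESeq2 67.2%, 82.1% and 93.9% with 13. The move back was scored only among simulated genes already called in B87+DMKG vs Control. Of 78 such genes made to move back with Nutlin-3, 76 were found, and 1 of 89 others was called in error. With Rita, where none was made to, 0 of 167 were. Changed genes missed in the first step are not part of these figures. Figures were drawn with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9). The p-values of rows with several genes, antisense genes and near-identical copies depend on how reads were assigned, which is not given in the sources used here.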

Results

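Messenger RNA was measured in H460 cells, an established human non-small cell lung cancer line, by sequencing poly(A)-selected RNA 6 h after treatment. The 31 libraries fall into 8 groups. Control cells were untreated per the labels (n = 4). B87 is BAY87-2243 at 1 µM, an inhibitor of complex I of the mitochondrial respiratory chain (n = 4). DMKG is dimethyl α-ketoglutarate at 5 mM, a cell-permeable ester of the tricarboxylic acid cycle intermediate α-ketoglutarate (n = 4). B87+DMKG is the combination (n = 4). Nutlin-3 at 30 µM occupies the p53-binding pocket of MDM2, the ubiquitin ligase that keeps p53 low (n = 3). Rita at 50 µM is a small molecule described as binding p53 and blocking its contact with MDM2 (n = 4). B87+DMKG+Nutlin-3 (n = 4) and B87+DMKG+Rita (n = 4) are the triple treatments. The series compares these treatments for their transcriptional effects in the setting of cell death, and its title names MDM2 inhibitors and the response to DMKG plus B87. The whole reads recovered from the normalized read counts were 33.4 M (B87 replicate 4) to 82.5 M (Rita replicate 2) per library, with a median of 63.1 M.

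Log2 fold changes below are differences of mean log2(normalized read count + 1), and the value after ± is the standard error from limma. A gene is said to rise or fall where limma's Benjamini-Hochberg adjusted p was under 0.05 over the 16259 table rows tested. Group levels are mean normalized read counts ± SD. Each library came from 2 pooled wells, and it is not stated that replicates came from separate experiments, so the p-values measure the spread between these samples, which may be technical. All changes are relative to the rest of the transcriptome, since no spike-in was used here. Scaling each library to the same total moved the median log2 fold change by between -0.254 (B87+DMKG+Rita vs Control) and 0.119 (combination beyond additive). Positions are on hg19, the build given in the file header.

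The first 2 principal components of the log2 values held 26.5% and 20.4% of the variance. Control and B87 libraries lay together, Rita and B87+DMKG+Rita libraries lay at the low end of component 1, and B87+DMKG libraries at its high end. Within groups, the correlation of log2 values between libraries was 0.964 to 0.993. DMKG replicates 1 and 2 lay apart from replicates 3 and 4, and the B87+DMKG libraries varied most in the share of reads from the mitochondrial genome (2.24% to 7.51%, against 1.84% ± 0.284 in Control, SD, n = 4).

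**Figure D1:**
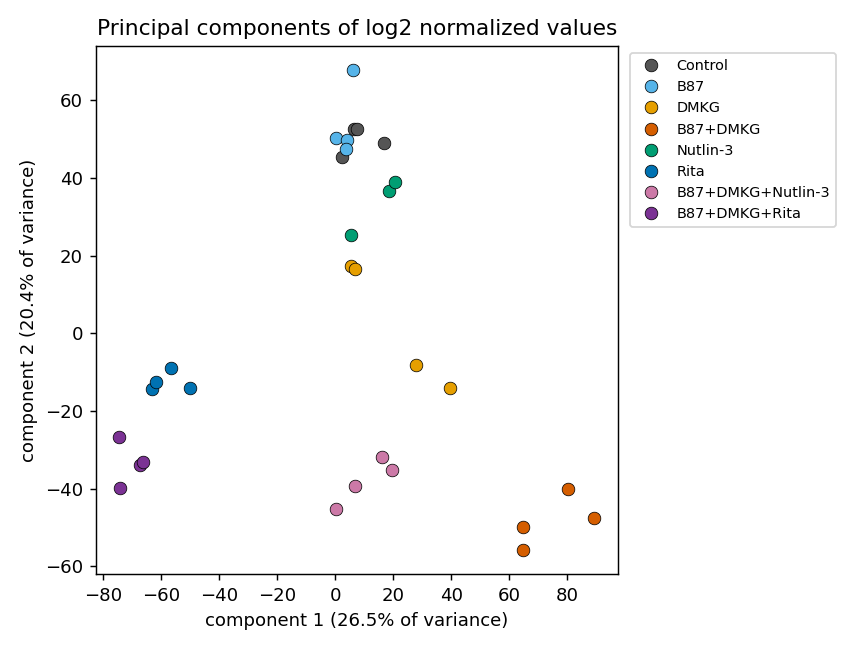
Principal components of log2(normalized read count + 1) over the rows tested; each point is 1 of the 31 libraries, coloured by group, and the axes give the component scores with the share of variance they hold (26.5% and 20.4%). Control and B87 libraries overlap, and DMKG libraries form a pair of pairs.

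B87 alone against Control asked what complex I inhibition does at the dose used in the combination. TXNIP, which encodes an inhibitor of thioredoxin that follows glucose availability (GSHG0000892, chromosome 1, 145438438 to 145442643), had the largest change of the called genes with a symbol, from 901 ± 236 in Control to 400 ± 92.8 in B87 (SD, n = 4 each), a log2 fold change of -1.15 ± 0.16 (limma adjusted p = 4.9e-04). TNS2, which encodes a focal adhesion protein, fell (-0.59 ± 0.11). EPGN, an epidermal growth factor receptor ligand (0.61 ± 0.10), OGT, the enzyme that attaches O-linked N-acetylglucosamine to proteins (0.50 ± 0.09), RNF19B (0.41 ± 0.08) and GID4 (0.37 ± 0.07) rose. With 1 row that has no symbol these were all the calls by limma, 7 in total (5 up, 2 down), while 904 rows had an unadjusted p under 0.05. The glycolysis list (0 of 21 members called over all genes, 1 up adjusted over the list alone) and the hypoxia list (0 of 23) had no member past the test, and no list was called with an estimated correlation. Under scaling of each library to the same total, the calls were 60% up against 71.4%. The count depended on the test and on single libraries: it was 30 with DESeq2 and 8 with edgeR on whole reads, 14 with only the groups compared, and 2 to 7 when 1 library was left out (2 without B87 replicate 4). Of the 34 other groupings of the same 8 libraries 1 gave as many calls, with 10, so chance was not excluded for this count. Not past the test were MDM2 (0.17 ± 0.09), CDKN1A (0.20 ± 0.10), GDF15 (-0.14 ± 0.18), HK2 (0.22 ± 0.09), SLC2A1 (0.28 ± 0.10), LDHA (0.03 ± 0.07), VEGFA (0.08 ± 0.11), CA9 (-0.47 ± 0.68), DDIT3 (-0.24 ± 0.25), ATF4 (0.17 ± 0.07), ASNS (-0.02 ± 0.12), TRIB3 (-0.10 ± 0.17), BBC3 (0.22 ± 0.18) and PARP1 (-0.03 ± 0.06). Each of EPGN, OGT, RNF19B, GID4 and TNS2 lost its call when 1 or more single libraries were left out, with an adjusted p of 0.0863, 0.103, 0.185, 0.103 and 0.158 without B87 replicate 4, whereas TXNIP did not in any setting. EPGN and OGT also lost it without Control replicate 2 (0.0562 and 0.0959). RNF19B lost it without any library but B87 replicate 2, GID4 without any but B87 replicate 3 and Control replicate 4, and TNS2 without any but B87 replicate 3. Scaling to the same total also lost OGT (0.0913), RNF19B (0.162) and GID4 (0.0592), and testing with no filter on low values lost TNS2 (0.0517).

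DMKG alone against Control moved 6725 rows (3184 up, 3541 down), 1691 of them by at least 1 on the log2 scale (746 up, 945 down). Genes known to be induced by low oxygen were among the largest rises: MIR210HG, the host transcript of a hypoxia-induced microRNA (6.97 ± 0.68), PFKFB4, a glycolytic regulator (4.69 ± 0.17), CA9, the carbonic anhydrase used as a hypoxia marker (4.67 ± 0.68), ANKRD37 (4.04 ± 0.24), STC1 (3.93 ± 0.14) and ANGPTL4 (3.87 ± 0.13). CA9 went from 1.68 ± 1.12 to 61.5 ± 12.3 normalized read counts (SD, n = 4 each). HK2, the hexokinase that starts glycolysis (GSHG0016590, chromosome 2, 75059782 to 75120479), went from 3860 ± 280 to 18954 ± 1597 (SD, n = 4 each; log2 fold change 2.29 ± 0.09, limma adjusted p = 1.4e-18), and the glucose transporters SLC2A3 (2.93 ± 0.10) and SLC2A1 (0.95 ± 0.10) rose with it. Of the 23 hypoxia genes tested 22 rose (22 adjusted over the list alone; camera adjusted p = 5.3e-08 with an estimated correlation). So did 19 of 21 glycolysis genes (20 adjusted over the list alone; adjusted p = 0.0087 with an estimated correlation). Immediate early genes also rose, 15 of 18 (15 adjusted over the list alone; adjusted p = 0.0041 with an estimated correlation), among them FOSB (2.69 ± 0.30), JUN (2.51 ± 0.11) and NR4A1 (2.41 ± 0.22). A rise was also called in 10 of 16 endoplasmic reticulum chaperone and unfolded protein genes (12 adjusted over the list alone; adjusted p = 0.023 with an estimated correlation), among them HERPUD1 (1.13 ± 0.12) and DNAJB9 (0.99 ± 0.11). Their median went from 0.308 to 0.196 with the same total in every library, with 8 up and 1 down.

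Other DMKG groups moved less evenly. Of 18 cholesterol genes 13 rose, such as INSIG1 (1.33 ± 0.13) and MSMO1 (1.26 ± 0.13), but the call by camera was lost with an estimated correlation (adjusted p = 0.059). The p53 target list went both ways, with 8 of 29 up and 9 down (9 and 9 adjusted over the list alone) and a median that changes sign with the scaling: BBC3, which encodes the pro-apoptotic protein PUMA (1.38 ± 0.18), CDKN1A, the cell cycle inhibitor p21 (0.59 ± 0.10), and GDF15 (0.66 ± 0.18) rose, and TRIAP1 fell (-0.66 ± 0.14). Among the largest falls were PPP1R10, a nuclear regulatory subunit of protein phosphatase 1 (GSHG0026444, chromosome 6, 30568179 to 30585084), from 3895 ± 345 to 204 ± 47.4 (SD, n = 4 each; log2 fold change -4.27 ± 0.13), SKIDA1 (-3.21 ± 0.21), the zinc finger gene ZNF658 (-3.13 ± 0.27), BCDIN3D (-2.81 ± 0.24), C17orf97 (-2.76 ± 0.19) and ZNF594 (-2.75 ± 0.17). OGDH, a subunit of the enzyme that uses α-ketoglutarate, rose (0.60 ± 0.05). With DMKG replicates 3 and 4 left out the count was 5023, and with 1 and 2 left out 6816. When each library was scaled to the same total, 31.6% of the calls were up against 47.3%. The naming rule also gave MTRNR2L9 (5.63 ± 1.64), SPDYE8P (3.69 ± 0.26), MT1G (3.42 ± 0.77), LDHA (0.62 ± 0.07), VEGFA (0.42 ± 0.11) and MDM2 (0.27 ± 0.09) as higher. Genes lower were HOXA7 (-2.77 ± 0.48), NUTM2B (-2.73 ± 0.59) and TRIB3 (-0.90 ± 0.17). The test was not passed by DDIT3 (-0.54 ± 0.25), ATF4 (-0.08 ± 0.07), ASNS (-0.29 ± 0.12), TXNIP (0.32 ± 0.16) and PARP1 (0.13 ± 0.06). These calls depended on the setting. Without Control replicate 3, DDIT3 (-0.976, adjusted p = 5.0e-05), ASNS (-0.458, 0.000723) and ATF4 (-0.176, 0.0355) were called lower, and without Control replicate 1 TXNIP was called higher (0.43, 0.0446). DESeq2, edgeR and scaling to the same total also called DDIT3 (-0.675, -0.68 and -0.652) and ASNS (-0.313, -0.321 and -0.399). Quantile normalization called ASNS (-0.327, 0.0408) and ATF4 (-0.236, 0.00673), scaling to the same total called ATF4 (-0.196, 0.0215), and DESeq2 called PARP1 (0.129, 0.0389). DDIT3 was also called without DMKG replicates 3 and 4 (-0.797, 0.0458). Without DMKG replicates 3 and 4 the calls of MT1G (0.782, adjusted p = 0.215), MTRNR2L9 (5.12, 0.0605), GDF15 (0.554, 0.0634) and VEGFA (0.287, 0.104) were lost, and that of MDM2 was lost without replicates 1 and 2 (0.198, 0.136) and with the same total in every library (0.16, 0.184). DESeq2 did not call MTRNR2L9 (4.11, 0.0929).

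**Figure D2:**
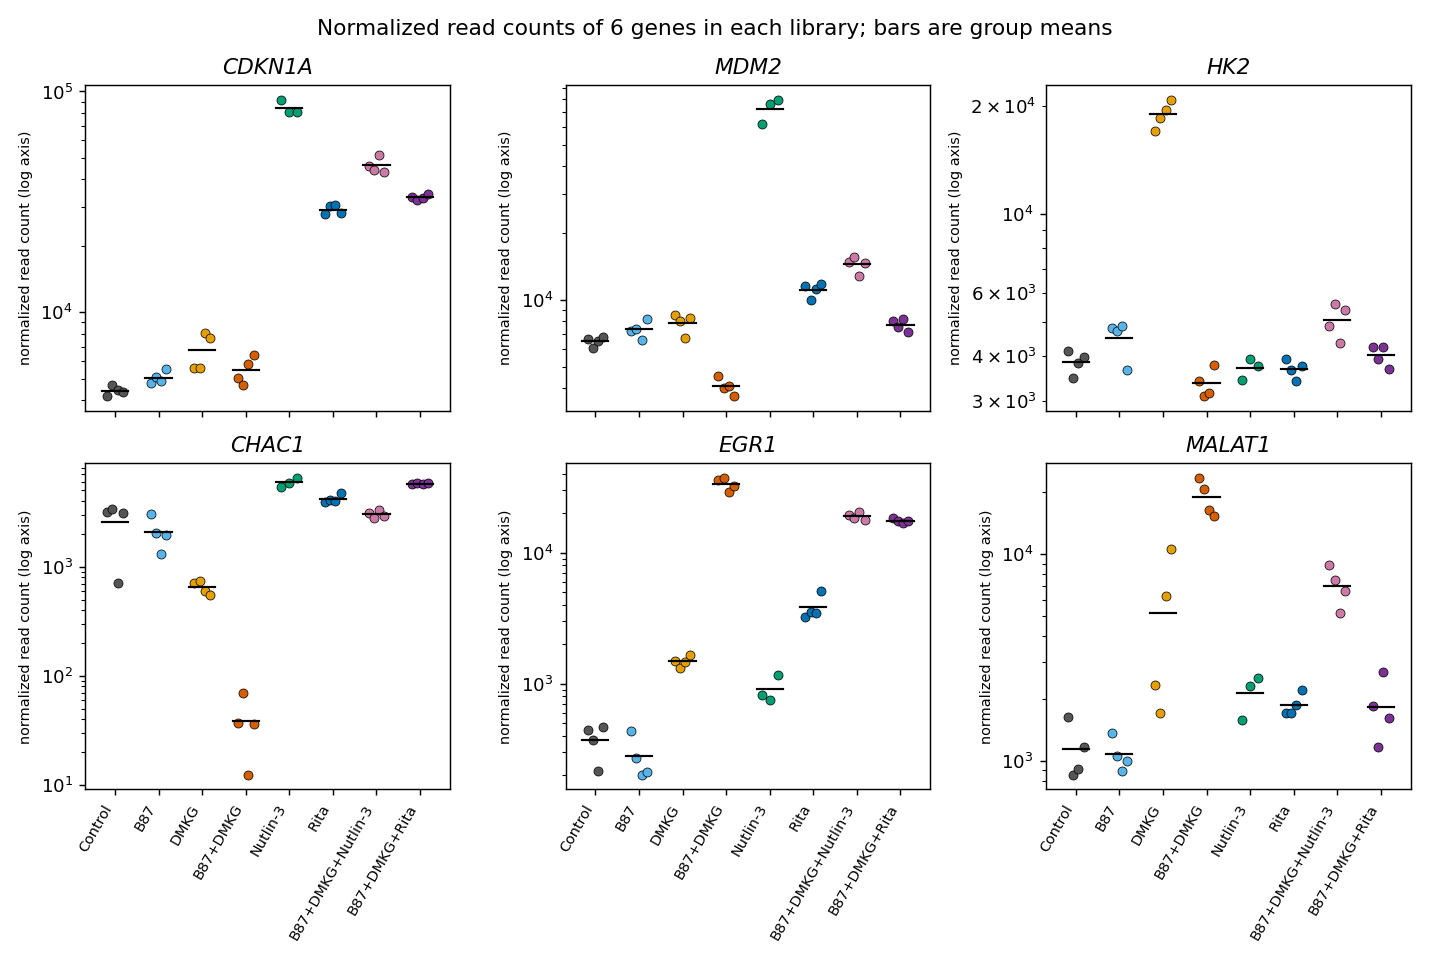
Normalized read counts (log axis) of CDKN1A, MDM2, HK2, CHAC1, EGR1 and MALAT1 in each of the 31 libraries by group; points are libraries and bars are group means. HK2 is high in DMKG alone (mean 18954) and near the Control mean of 3860 in B87+DMKG (3359), and CHAC1 is lowest in B87+DMKG (38.8).

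B87+DMKG against Control is the combination named in the title of the series. It moved 9922 rows (4912 up, 5010 down), 3391 of them by at least 1 (2073 up, 1318 down). CHAC1, a glutathione-degrading enzyme induced by ATF4 (GSHG0009793, chromosome 15, 41245636 to 41248717), fell from 2589 ± 1258 to 38.8 ± 23.3 (SD, n = 4 each; log2 fold change -6.02 ± 0.36, limma adjusted p = 1.1e-14), with 1 Control library already low at 710. The growth-response transcription factor EGR1 (GSHG0024271, chromosome 5, 137801169 to 137805189) went from 374 ± 115 to 33495 ± 3626 (SD, n = 4 each; 6.54 ± 0.20, limma adjusted p = 4.0e-21), and FOSB (4.64 ± 0.30), FOS (4.03 ± 0.20) and EGR3 (3.43 ± 0.81) rose with it. In all 15 of 18 immediate early genes rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 4.3e-08 with the preset and 0.081 with an estimated correlation). Other large rises were in the metallothioneins MT1G (6.64 ± 0.77) and MT1F (4.33 ± 0.55), metal-binding proteins whose near-identical copies can share reads, in the nuclear RNA MALAT1 (4.08 ± 0.34), in RGPD1 (4.37 ± 1.16), a member of a duplicated family, and in the antisense gene ASMTL-AS1 (4.34 ± 0.71). Among the falls were UBL3, which encodes a membrane-anchored ubiquitin-like protein (-3.59 ± 0.14), NANOS1 (-3.49 ± 0.55), KBTBD8 (-3.45 ± 0.69), CUL3, a ubiquitin ligase scaffold (-3.29 ± 0.10), the peptide hormone gene ADM2 (-3.22 ± 0.26), the antisense gene ST20-AS1 (-3.42 ± 0.58) and MTRNR2L8 (-4.16 ± 0.51), a nuclear copy of mitochondrial 16S rRNA.

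The integrated stress response list (targets of ATF4) had 19 of 23 genes down and 1 up (19 and 2 adjusted over the list alone). TRIB3 (-2.24 ± 0.17), SESN2 (-2.18 ± 0.20), ASNS, asparagine synthetase (-1.54 ± 0.12), and ATF4 itself (-0.73 ± 0.07) fell, and PPP1R15A rose (2.63 ± 0.16). Nutrient and redox groups pointed down as well: 9 of 12 cytosolic aminoacyl-tRNA synthetases, such as IARS (-0.80 ± 0.06), and 11 of 17 NRF2 targets, such as GCLM (-1.34 ± 0.09) and HMOX1 (-1.02 ± 0.13), were lower. Of 29 p53 targets 16 fell and 3 rose (16 and 3 adjusted over the list alone), with SESN2, SPATA18 (-1.78 ± 0.29), PMAIP1, which encodes the pro-apoptotic protein NOXA (-1.58 ± 0.15), and MDM2 (GSHG0006826, chromosome 12, 69195239 to 69239324) falling, the last from 6525 ± 328 to 4081 ± 355 (SD, n = 4 each; -0.68 ± 0.09). CDKN1A rose (0.31 ± 0.10). Of 27 cell death regulators 16 fell and 1 rose, including the death receptor gene TNFRSF10B (-1.40 ± 0.13), BMF (-1.82 ± 0.53) and the apoptosis inhibitor gene BIRC2 (-1.29 ± 0.16). None of these lists was called with an estimated correlation (adjusted p = 0.29 for the stress response, 0.29 for the synthetases, 0.24 for NRF2 targets, 0.098 for p53 targets and 0.081 for cell death regulators), although the camera test with the preset called each of them.

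Lists that camera did not call in this comparison are given for completeness of the groups fixed beforehand. Of 23 hypoxia genes 12 fell and 3 rose, including the oxygen sensors EGLN1 (-1.38 ± 0.12) and EGLN3 (-1.20 ± 0.17), and of 21 glycolysis genes 9 fell and 4 rose. HK2 (-0.20 ± 0.09) and CA9 (-0.06 ± 0.68) did not pass the test. Of 21 tricarboxylic acid cycle and glutamine genes 11 fell and 3 rose, and of 30 nuclear-encoded complex I genes 12 fell and 4 rose. Of 18 cholesterol genes 8 rose and 4 fell. Of 15 NF-kB and inflammatory genes 9 rose and 4 fell, with IL1A (-2.58 ± 0.25) and IL1B (-2.35 ± 0.39) the largest changes. Of 21 mitosis genes 10 rose and 8 fell, with the proliferation marker MKI67 up (1.25 ± 0.14) and CDK1 down (-0.71 ± 0.07). DNA replication genes (6 up and 7 down of 21), endoplasmic reticulum genes (5 up and 3 down of 16), heat shock genes (4 up and 3 down of 11), nucleolar genes (3 up and 7 down of 18), glucose-sensing genes (3 up and 2 down of 6, with a median that changes sign with the scaling) and fibroblast markers (2 up and 2 down of 5) went both ways. Only CD14 (-1.69 ± 0.28) of 8 leukocyte markers and KDR (1.95 ± 0.59) of 7 endothelial markers were expressed highly enough to be tested, and none of the 13 mitochondrially encoded protein genes entered the test under its symbol. Called lower were DDIT3 (-0.93 ± 0.25), VEGFA (-0.84 ± 0.11), SLC2A1 (-0.75 ± 0.10), GDF15 (-0.62 ± 0.18) and PARP1 (-0.28 ± 0.06). No change was called for LDHA (-0.14 ± 0.07), TXNIP (-0.31 ± 0.16) and BBC3 (-0.31 ± 0.18). TXNIP was called lower without Control replicate 3 (-0.523, adjusted p = 0.00281), without B87+DMKG replicate 2 (-0.456, 0.017) and with edgeR (-0.37, 0.0436). LDHA was called lower without B87+DMKG replicate 1 (-0.18, 0.0407) or 2 (-0.196, 0.0226), with edgeR (-0.172) and with the same total (-0.159), and HK2 without B87+DMKG replicate 4 (-0.261), without Control replicate 2 (-0.25) and with edgeR (-0.235).

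The contrast of the combination with the sum of its parts asked whether B87+DMKG exceeded B87 plus DMKG on the log2 scale. It was past the test for 7927 rows (4006 up, 3921 down), 3217 by at least 1 (2044 up, 1173 down). The DMKG rise of hypoxia genes was not seen with B87 added: 22 of 23 were lower than additive (22 adjusted over the list alone; camera adjusted p = 7.8e-07 with an estimated correlation), with ANKRD37 (-5.16 ± 0.33), CA9 (-4.26 ± 0.96), ANGPTL4 (-3.71 ± 0.18) and KDM3A, a histone demethylase (-3.14 ± 0.15). Outside this list MIR210HG was lower too (-5.88 ± 0.96). Glycolysis followed, 18 of 21 lower (19 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation), with PFKFB4 (-3.995 ± 0.24), SLC2A3 (-3.13 ± 0.14) and HK2 (-2.71 ± 0.13). Also lower were 18 of 29 p53 targets, with 2 higher (18 and 2 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation), with SESN1 (-2.18 ± 0.22), CCNG1 (-2.15 ± 0.21), BBC3 (-1.91 ± 0.26) and MDM2 (-1.13 ± 0.12). The same held for 16 of 21 tricarboxylic acid cycle genes (16 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation), with SUCLA2 (-1.17 ± 0.12). In the other direction PPP1R10 (5.19 ± 0.18), EGR1 (4.92 ± 0.28), TCHH (4.57 ± 0.44), GNB3 (4.54 ± 0.51) and the histone gene HIST3H2BB (4.30 ± 0.25) were higher than additive. PPP1R10 fell with DMKG and stood at 6716 ± 1026 in B87+DMKG (SD, n = 4). CHAC1 was lower than additive (-4.11 ± 0.50). When each library was scaled to the same total, 61.3% of the calls were up against 50.5%. Other genes of the naming rule that were higher than additive were ASMTL-AS1 (4.69 ± 1.006), GOLGA6L5P (4.29 ± 0.81) and LHX4-AS1 (4.10 ± 0.35). Those lower than additive were MTRNR2L9 (-7.02 ± 2.32), MTRNR2L8 (-4.57 ± 0.72), CCNG2 (-4.53 ± 0.33), SLC2A1 (-1.99 ± 0.14), VEGFA (-1.34 ± 0.16), TRIB3 (-1.24 ± 0.24), ASNS (-1.24 ± 0.17), GDF15 (-1.14 ± 0.26), ATF4 (-0.82 ± 0.10), LDHA (-0.80 ± 0.10), CDKN1A (-0.48 ± 0.14) and PARP1 (-0.38 ± 0.08). Not past the test were DDIT3 (-0.16 ± 0.35) and TXNIP (0.53 ± 0.23). TXNIP was called higher without B87 replicate 4 (0.672), B87+DMKG replicates 1 (0.582) or 4 (0.613), Control replicate 3 (0.737, adjusted p = 0.00288) or DMKG replicate 2 (0.591), and with DESeq2 (0.576), edgeR (0.548), quantile normalization (0.568), the same total (0.646) and the replicate block (adjusted p = 0.0499). The call of CDKN1A (-0.235, adjusted p = 0.105) was lost without DMKG replicates 3 and 4, and that of MTRNR2L9 with DESeq2 (-5.19, 0.129).

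DMKG and B87+DMKG moved many of the same genes against Control. In both, 1702 rows rose and 1853 fell, where independent lists would share 962 and 1091, while 557 and 505 rows moved in opposite directions. Both comparisons use the same Control libraries. With the Control libraries split, the shared calls were 1104 up and 1364 down, and unchanged groups simulated against these controls shared 0, a count that carries no weight because such groups have almost no calls. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.444 (0.383 with split controls, 0.493 in the simulation). Their covariance was 0.309 (0.278 with split controls), against 0.0391 from shared controls in the simulation.

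Nutlin-3 alone against Control moved 6359 rows (3000 up, 3359 down), 1223 by at least 1 (676 up, 547 down). Genes known to be driven by p53 rose together, 26 of 29 (26, with 1 down, adjusted over the list alone; camera adjusted p = 2.4e-08 with an estimated correlation). CDKN1A (GSHG0025686, chromosome 6, 36644237 to 36655114) went from 4414 ± 210 (SD, n = 4) to 84255 ± 6459 (SD, n = 3; log2 fold change 4.25 ± 0.11, limma adjusted p = 6.9e-24) and MDM2 from 6525 ± 328 to 72583 ± 9402 (3.47 ± 0.09, limma adjusted p = 5.4e-23). BTG2, an antiproliferative gene (4.37 ± 0.11), the stress cytokine GDF15 (3.84 ± 0.20), TP53INP1 (3.75 ± 0.19), BBC3 (2.58 ± 0.20) and the death receptor FAS (2.56 ± 0.15) were among them. Outside that list NECTIN4 (4.79 ± 0.53), NUPR1 (4.13 ± 0.26), WDR63 (4.12 ± 0.44) and INPP5D (3.87 ± 0.30) were among the largest rises. Endoplasmic reticulum genes rose, 14 of 16 (14 adjusted over the list alone; adjusted p = 4.3e-05 with an estimated correlation), with DNAJB9 (2.91 ± 0.12) and HERPUD1 (2.60 ± 0.13). So did 10 of 12 aminoacyl-tRNA synthetases (11 adjusted over the list alone; adjusted p = 0.013 with an estimated correlation), with SARS (1.05 ± 0.08). Integrated stress response genes rose in 19 of 23 cases (20 adjusted over the list alone), but this call was lost with an estimated correlation (adjusted p = 0.11). DNA replication and S phase genes fell in 15 of 21 cases and rose in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.0035 with an estimated correlation), among them the cyclins CCNE2 (-2.37 ± 0.17) and CCNE1 (-1.95 ± 0.09) and the licensing factor CDT1 (-1.29 ± 0.14), while LRRC3 (-3.31 ± 0.37) and DGAT2, which makes triglyceride (-2.92 ± 0.18), were among the largest falls. Scaled to the same total, 30.5% of the calls were up against 47.2%. The naming rule also gave DDIT3 (1.72 ± 0.27), TXNIP (1.496 ± 0.17), ASNS (0.92 ± 0.13), TRIB3 (0.75 ± 0.18), VEGFA (0.58 ± 0.12) and ATF4 (0.58 ± 0.08) as higher. Genes lower were SERTAD4 (-2.75 ± 0.31), FAM111B (-2.42 ± 0.18), CAND2 (-2.23 ± 0.34), SPHK1 (-2.22 ± 0.31), PAQR8 (-2.19 ± 0.31), SLC2A1 (-0.57 ± 0.11) and PARP1 (-0.34 ± 0.06). The test was not passed by HK2 (-0.06 ± 0.10), LDHA (0.02 ± 0.08) and CA9 (-0.68 ± 0.73).

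Rita alone against Control moved 8468 rows (4187 up, 4281 down), 2272 by at least 1 (992 up, 1280 down). Among the largest rises were FAM71A (8.14 ± 0.41), C1orf116 (5.72 ± 0.49), FOSB (4.75 ± 0.30), the stress-induced factor ATF3 (4.23 ± 0.25), NHLH1 (4.03 ± 0.24) and JUN (3.52 ± 0.11). Of 29 p53 targets 21 rose (21 adjusted over the list alone; camera adjusted p = 0.00026 with an estimated correlation), with BTG2 (3.41 ± 0.10), GDF15 (3.18 ± 0.18), CDKN1A (2.73 ± 0.10) and PMAIP1 (2.56 ± 0.15). MDM2 rose by 0.76 ± 0.09, to 11099 ± 789 (SD, n = 4). Integrated stress response genes (18 of 23 up) and immediate early genes (13 of 18 up) were not called with an estimated correlation (adjusted p = 0.26 and 0.24). Large falls were in RGL1 (-3.57 ± 0.46), the Notch coactivators MAML2 (-3.32 ± 0.26) and MAML3 (-3.06 ± 0.16), PDE7B (-3.28 ± 0.17), STARD13 (-3.13 ± 0.38), SLC10A7 (-3.07 ± 0.19) and SOX6 (-3.03 ± 0.27). Across 13334 genes the Spearman correlation of log2 fold change with the distance from gene start to end was -0.512. In the 10% of genes with the shortest spans (median 2.63 kb) the median change was 0.29 and 10.5% fell, and in the 10% with the longest (median 271 kb) it was -0.77 and 69.3% fell. With Nutlin-3 the correlation was -0.0135, but its single libraries gave -0.183 (replicate 1), 0.0638 and 0.0469, and B87+DMKG+Nutlin-3 vs Control gave -0.224. The share of reads from the 45S ribosomal RNA row was 4.12% ± 0.308 in Rita against 2.399% ± 0.112 in Control (SD, n = 4 each), and scaled to the same total 30.9% of the calls were up against 49.4%. Also higher were HIC1 (3.65 ± 0.69), GUCA1B (3.55 ± 0.34), DDIT3 (2.03 ± 0.25), BBC3 (1.76 ± 0.18), ASNS (1.42 ± 0.12), TXNIP (1.08 ± 0.16), VEGFA (0.75 ± 0.11) and ATF4 (0.49 ± 0.07). Called lower were ZNF407 (-3.06 ± 0.15) and SLC2A1 (-0.98 ± 0.10). No change was called for HK2 (-0.07 ± 0.09), LDHA (0.03 ± 0.07), CA9 (0.37 ± 0.68), TRIB3 (0.33 ± 0.17) and PARP1 (-0.04 ± 0.06). The direction of LDHA turned with the same total in every library (-0.144, adjusted p = 0.0422), and HK2 (-0.242, 0.0432) and PARP1 (-0.215, 0.00376) were then called lower, PARP1 also with quantile normalization (-0.168, 0.0233). TRIB3 was called higher without Rita replicate 4 (0.453, 0.0335).

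**Figure D3:**
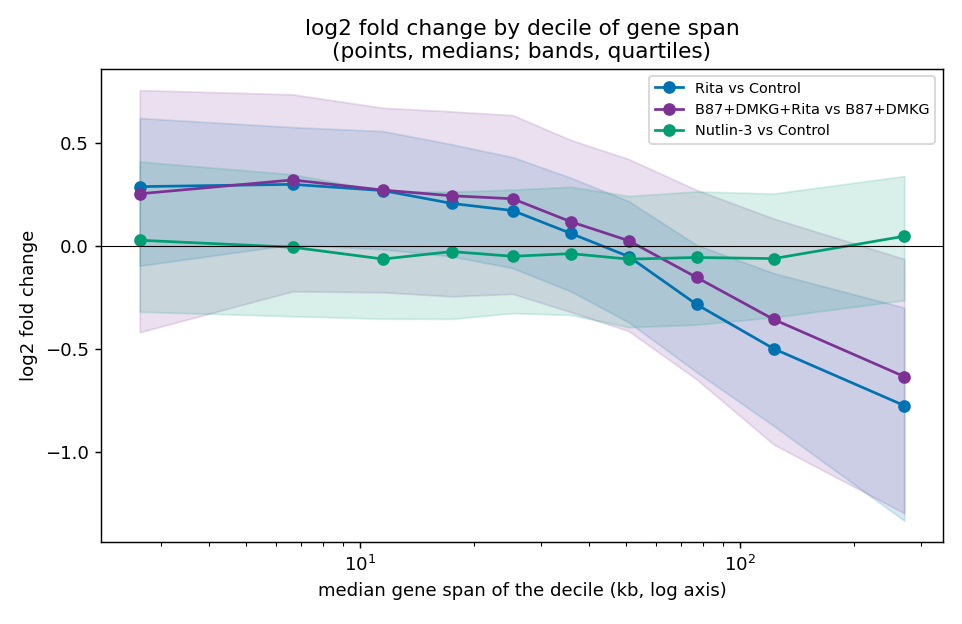
Median log2 fold change (points) and quartiles (bands) by decile of gene span in kb (log axis) for Rita vs Control, B87+DMKG+Rita vs B87+DMKG and Nutlin-3 vs Control. The Rita medians go from 0.29 in the shortest decile to -0.77 in the longest, and the Nutlin-3 medians stay near 0.

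Nutlin-3 and Rita, the compounds directed at MDM2 and p53, were given at different doses. Against Control, 1490 rows rose and 1471 fell with both, where independent lists would share 773 and 884 (1018 and 1031 with split controls). Simulated unchanged groups, which have almost no calls, shared 0. The correlation across genes was 0.335 (0.262 with split controls, 0.462 in the simulation). The covariance was 0.174 (0.143 with split controls), against 0.0392 from shared controls in the simulation.

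Adding Nutlin-3 to B87+DMKG changed 9570 rows (4314 up, 5256 down), 2973 by at least 1 (681 up, 2292 down). CHAC1 rose from 38.8 ± 23.3 to 3040 ± 229 (SD, n = 4 each; log2 fold change 6.48 ± 0.36, limma adjusted p = 1.9e-15), and other large rises were in GDF15 (5.00 ± 0.18), the epithelial factor ELF3 (4.49 ± 0.46), DDIT4, an inhibitor of mTOR signalling (4.40 ± 0.12), CYP1A1, a target of the aryl hydrocarbon receptor (4.26 ± 0.34), and TRIB3 (3.37 ± 0.17). Of 29 p53 targets 23 rose and 2 fell (24 and 2 adjusted over the list alone; camera adjusted p = 6.9e-05 with an estimated correlation), with SESN2 (3.23 ± 0.20), CDKN1A (3.08 ± 0.10), BBC3 (2.56 ± 0.18) and MDM2 (1.83 ± 0.09). Of 23 hypoxia genes 17 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.0013 with an estimated correlation), with BHLHE40 (2.54 ± 0.10) and ADM (2.23 ± 0.09). Of 23 integrated stress response genes 19 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 0.086 with an estimated correlation). Of 21 glycolysis genes 17 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.086 with an estimated correlation). The metallothioneins MT1G (-5.80 ± 0.77) and MT1F (-3.89 ± 0.55), the heat shock gene HSPA1A (-3.89 ± 0.22), the antisense gene LHX4-AS1 (-3.95 ± 0.25), GNB3 (-3.51 ± 0.36) and ZNF469 (-3.46 ± 0.12) fell. EGR2 fell (-3.19 ± 0.37) and IER3 rose (2.52 ± 0.13), and the 18 immediate early genes went both ways (3 up, 7 down). Quantile normalization gave 56% of calls up and scaling to the same total 31.9%, against 45.1%. Other genes of the naming rule that were higher were MTRNR2L8 (4.47 ± 0.51), LINC01433 (3.54 ± 0.68), DDIT3 (2.88 ± 0.25), ASNS (1.48 ± 0.12), SLC2A1 (1.196 ± 0.10), VEGFA (0.69 ± 0.11), HK2 (0.59 ± 0.09), ATF4 (0.55 ± 0.07) and LDHA (0.49 ± 0.07). Those lower were ASMTL-AS1 (-3.64 ± 0.71), FAM229A (-3.37 ± 0.30) and PARP1 (-0.83 ± 0.06). Not past the test were CA9 (1.34 ± 0.68; called without B87+DMKG replicate 2 at 1.71, adjusted p = 0.0418) and TXNIP (-0.13 ± 0.16). The call of LDHA was lost with quantile normalization (0.127, adjusted p = 0.116).

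Adding Rita to B87+DMKG changed 10937 rows (5383 up, 5554 down), 4286 by at least 1 (1515 up, 2771 down). Among the largest rises were FAM71A (9.02 ± 0.41), CHAC1 (7.399 ± 0.36), C11orf96 (5.14 ± 0.64), ADM2 (4.39 ± 0.26), GDF15 (4.36 ± 0.18) and PMAIP1 (4.32 ± 0.15), and CHAC1 reached 5744 ± 58.8 (SD, n = 4). Of 29 p53 targets 23 rose and 2 fell (23 and 2 adjusted over the list alone; camera adjusted p = 0.00088 with an estimated correlation). Of 23 hypoxia genes 17 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 0.034 with an estimated correlation), with VEGFA (1.74 ± 0.11). Of 21 tricarboxylic acid cycle genes 19 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 0.048 with an estimated correlation), with SUCLG1 (1.17 ± 0.10) and IDH2 (0.88 ± 0.11). Their median went from 0.476 to 0.298 (15 up, 1 down) with quantile normalization and 0.235 (11 up, 1 down) with the same total. Integrated stress response genes rose in 20 of 23 cases (20 adjusted over the list alone; adjusted p = 0.071 with an estimated correlation), with ATF3 (4.21 ± 0.25), DDIT3 (3.53 ± 0.25), ASNS (2.88 ± 0.12) and ATF4 (1.40 ± 0.07). Of 21 mitosis genes 13 fell and 4 rose (14 and 4 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), with CENPE (-1.83 ± 0.20), MKI67 (-1.54 ± 0.14) and AURKA (-1.13 ± 0.06). LHX4-AS1 (-5.50 ± 0.25), MAML2 (-4.82 ± 0.26), MAML3 (-4.53 ± 0.16), RGL1 (-4.54 ± 0.46) and the Hedgehog effector GLI2 (-4.44 ± 0.18) fell, as did RGPD1 (-6.61 ± 1.16) and GOLGA8A (-4.75 ± 0.45), both from families of near-identical copies. The 45S ribosomal RNA share was 4.54% ± 0.434 in B87+DMKG+Rita against 2.11% ± 0.780 in B87+DMKG (SD, n = 4 each), and scaled to the same total 32.7% of the calls were up against 49.2%. The naming rule also gave MTRNR2L9 (5.00 ± 1.64), MTRNR2L8 (4.27 ± 0.51), TRIB3 (3.19 ± 0.17), BBC3 (2.67 ± 0.18), CDKN1A (2.61 ± 0.10), MDM2 (0.92 ± 0.09), LDHA (0.40 ± 0.07), HK2 (0.26 ± 0.09) and PARP1 (0.20 ± 0.06) as higher. Genes lower were MT1G (-4.79 ± 0.77) and TXNIP (-0.61 ± 0.16). The test was not passed by SLC2A1 (0.07 ± 0.10) and CA9 (1.18 ± 0.68; called without B87+DMKG+Rita replicate 3 at 1.66, adjusted p = 0.0403). With the same total in every library the direction of PARP1 turned (-0.047, adjusted p = 0.512) and the call of HK2 was lost (0.02, 0.872), and with quantile normalization those of LDHA (0.002, 0.981), HK2 (0.128, 0.233) and PARP1 (0.016, 0.828) were lost. DESeq2 did not call MTRNR2L9 (2.97, adjusted p = 0.191).

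The additions shared most of their direction. On top of B87+DMKG, 3113 rows rose and 3383 fell with both compounds, where independent lists would share 1428 and 1795 (2427 and 2707 with the B87+DMKG libraries split). Simulated unchanged groups, with almost no calls to share, gave 0. The covariance of the log2 fold changes was 0.729 (0.665 split), against 0.0389 from shared libraries in the simulation (correlation across genes 0.672, 0.581 split, 0.496 simulated).

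**Figure D4:**
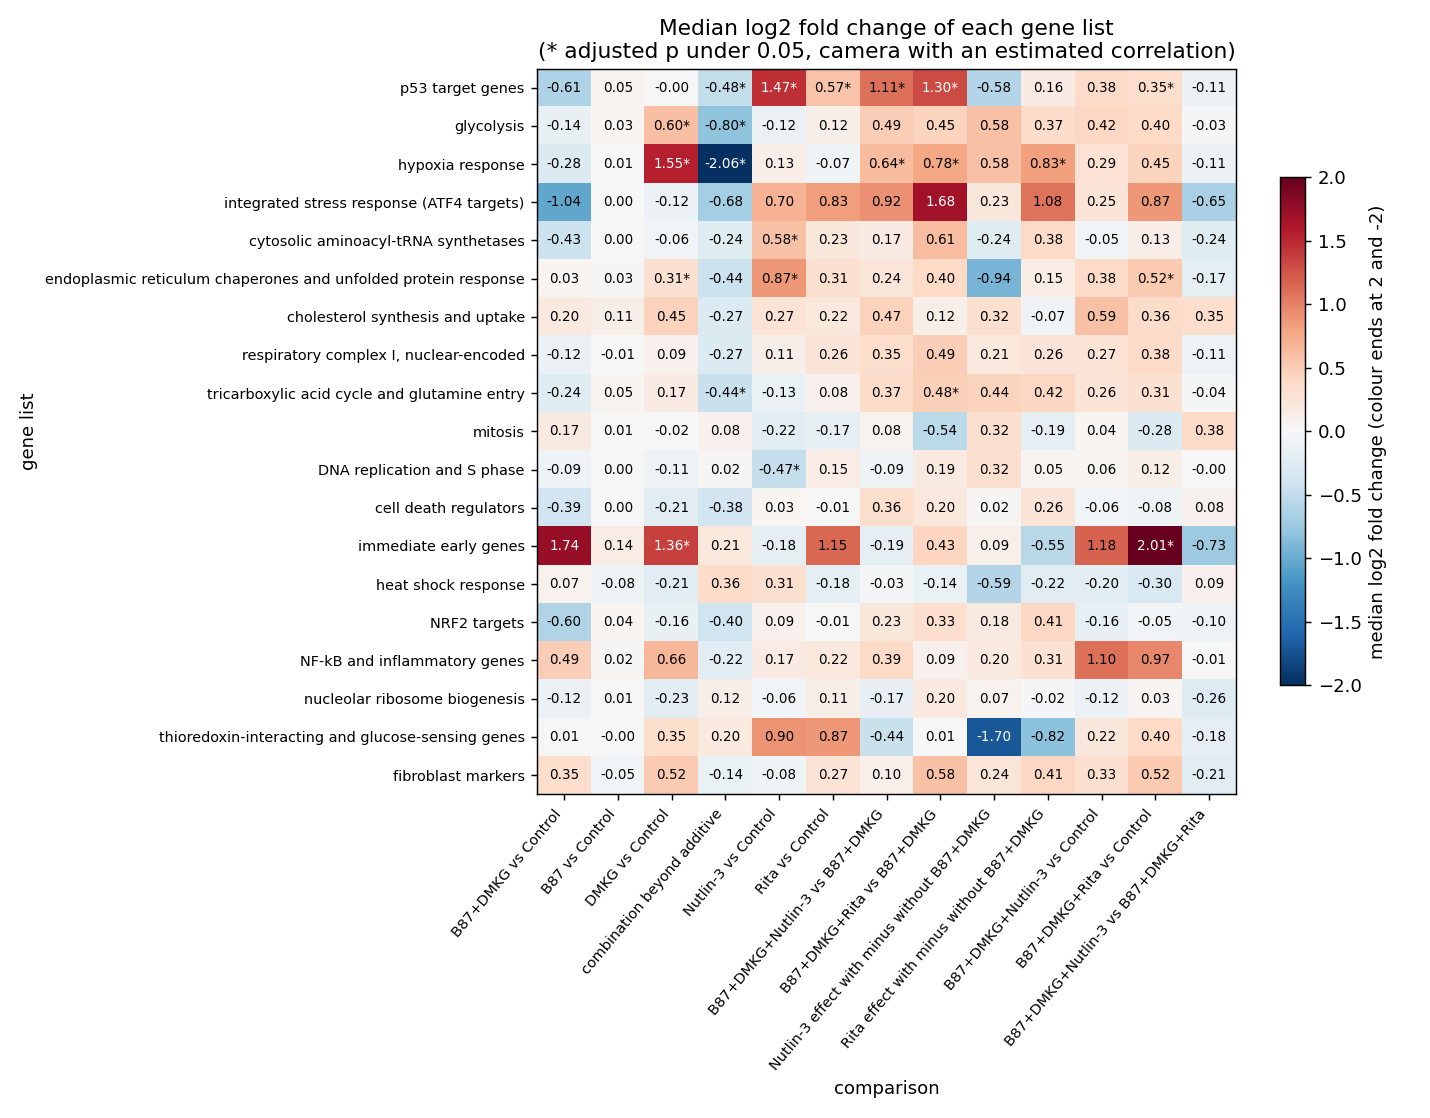
Median log2 fold change of the tested members of 19 gene lists (vertical) in 13 comparisons (horizontal); the colour scale ends at 2 and -2, and a star marks an adjusted p under 0.05 by camera with an estimated correlation. Stars stand in 22 cells, and none of these medians changed sign under quantile normalization or scaling to the same total; medians without a star can change sign.

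The question in the title of the series was addressed by following the 9922 rows changed by B87+DMKG. With Nutlin-3 added, 4960 of them (49.99%) changed in the opposite direction, 2688 of the risen and 2272 of the fallen, while 1513 (15.2%) moved further from Control. Independent lists would give 1588 and 1329 opposite calls, since most rows were called in the second step. With Rita, 6011 (60.6%) changed in the opposite direction, 3008 of the risen and 3003 of the fallen, and 1249 (12.6%) moved further. Here independent lists would give 1678 and 1659 opposite calls. A large part of each share thus follows from the number of calls alone. Both compounds moved back 3976 (40.1%) and neither moved back 2927, where both sets use the same Control and B87+DMKG libraries, so this overlap was not tested. Of the rows moved back by Nutlin-3, 2869 (57.8%) were no longer called against Control, 1174 (23.7%) were still called on the same side and 917 (18.5%) were called on the other side. For Rita these were 3116 (51.8%), 1193 (19.8%) and 1702 (28.3%). CHAC1 and TRIB3 moved back with both compounds, but TRIB3 was then called above Control in both triple treatments. CHAC1 with Rita also stood above the Control libraries (lowest library 5674, against 3369 in the highest Control library). EGR1 moved back too, from 33495 ± 3626, and stayed above the 374 ± 115 of Control, at 19097 ± 1180 with Nutlin-3 and 17441 ± 589 with Rita (SD, n = 4 each). The B87+DMKG libraries enter both steps, which by chance gives opposite signs. With these libraries split between the steps the shares were 40.5% to 47.0% for Nutlin-3 and 50.3% to 59.3% for Rita, with 1.76 to 3.68 (Nutlin-3) and 2.66 to 5.99 (Rita) opposite calls for each call in the same direction. Unchanged groups simulated with the libraries shared gave at most 0.00983% and 0%, but such groups have almost no calls to share. Of the rows moved back, Nutlin-3 alone made the same call in 380 (7.66%), the opposite call in 1838 and no call in 2742 (55.3%). Rita alone made the same call in 1441 (24.0%), the opposite call in 1217 and no call in 3353 (55.8%). The log2 fold changes of the 2 steps correlated across genes at -0.584 for Nutlin-3 (-0.484 split, -0.497 simulated) and -0.638 for Rita (-0.555 split, -0.499 simulated). Their covariances were -0.530 and -0.742 (-0.467 and -0.679 split), against -0.0391 and -0.0394 from shared libraries in the simulation. The simulation gave all groups the same spread per gene, although B87+DMKG varied most (median SD 0.249), so the shared part may be larger.

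**Figure D5:**
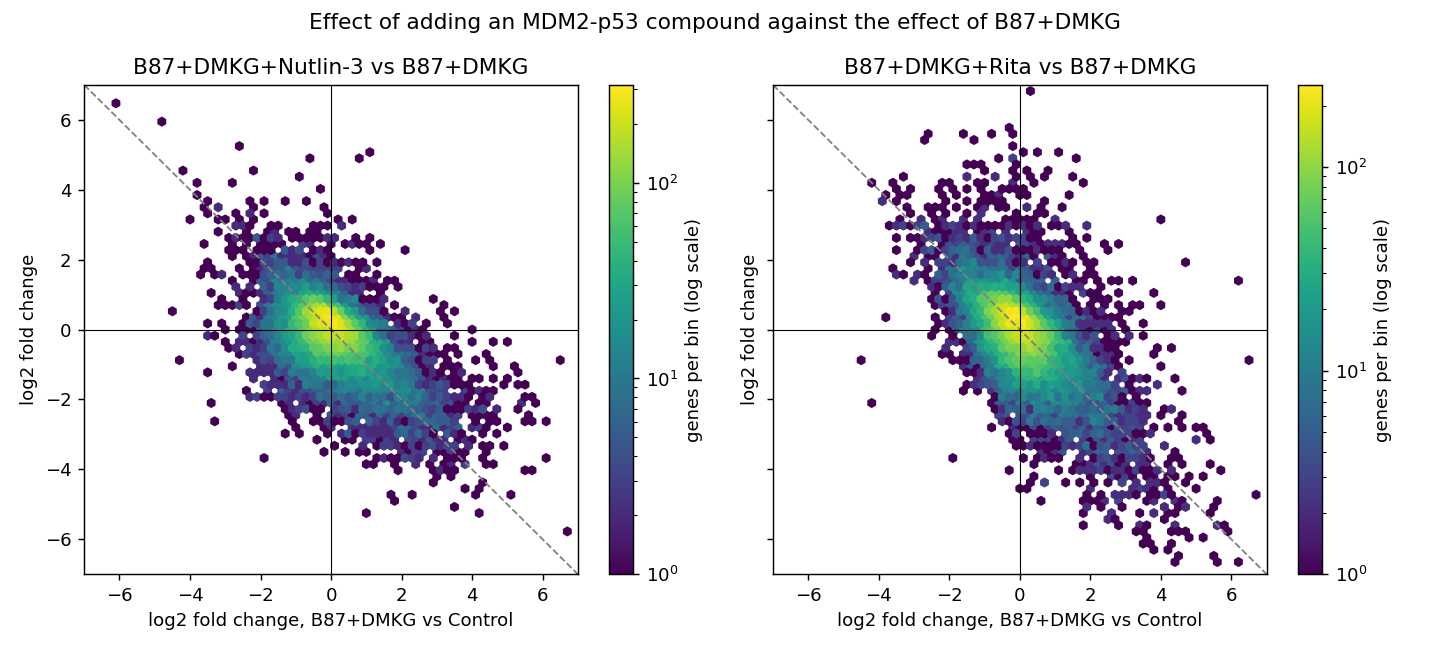
Log2 fold change on adding Nutlin-3 (left) or Rita (right) to B87+DMKG (vertical) against the log2 fold change of B87+DMKG vs Control (horizontal), as counts of rows per hexagon (log colour scale); the dashed line marks an exact return to the Control level. The correlations are -0.584 and -0.638, part of which comes from the shared B87+DMKG libraries.

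Interaction contrasts asked whether each compound acted differently with and without B87+DMKG. For Nutlin-3 the difference was past the test for 9259 rows (4285 up, 4974 down; 4456 by at least 1, 1590 up and 2866 down), and under quantile normalization the median over all rows moved by 0.157 and 55.1% of the calls were up against 46.3%. CHAC1 (5.06 ± 0.52) and DDIT4 (4.09 ± 0.18) had a higher Nutlin-3 effect with B87+DMKG present. MDM2 (-1.64 ± 0.13), CDKN1A (-1.17 ± 0.14), TP53INP1 (-3.05 ± 0.26) and FAS (-2.54 ± 0.20) had a lower one, and MDM2 reached 14461 ± 1215 in the triple treatment (SD, n = 4) against 72583 ± 9402 with Nutlin-3 alone (SD, n = 3). Of 29 p53 targets 17 had a lower and 6 a higher Nutlin-3 effect (19 and 6 adjusted over the list alone; adjusted p = 0.062 with an estimated correlation). Of 16 endoplasmic reticulum genes 13 had a lower and 3 a higher one (13 and 3 adjusted over the list alone; adjusted p = 0.057 with an estimated correlation), such as DNAJB9 (-2.02 ± 0.16). For Rita the difference was past the test for 7897 rows (3933 up, 3964 down; 3124 by at least 1, 1105 up and 2019 down). CHAC1 (6.48 ± 0.50), the amino acid transporter SLC38A2 (3.36 ± 0.28), UBL3 (3.13 ± 0.19), ADM2 (3.09 ± 0.37) and SESN2 (2.68 ± 0.28) had a higher Rita effect with B87+DMKG present. EGR1 (-4.32 ± 0.28) and MALAT1 (-4.17 ± 0.48) had a lower one, and both fell when Rita was added to B87+DMKG. CDKN1A (-0.12 ± 0.14) and MDM2 (0.16 ± 0.12) did not pass the test. Of 23 hypoxia genes 16 had a higher and 2 a lower Rita effect (17 and 2 adjusted over the list alone; camera adjusted p = 0.012 with an estimated correlation). Also higher in the Nutlin-3 interaction were MTRNR2L8 (5.04 ± 0.75), MIR210HG (4.12 ± 0.99), ELF3 (4.11 ± 0.67), LINC01433 (3.94 ± 1.00), ATOH8 (3.90 ± 0.31), SAMD11 (3.79 ± 0.46), TRIB3 (2.62 ± 0.25), SLC2A1 (1.76 ± 0.15), GDF15 (1.16 ± 0.27), DDIT3 (1.16 ± 0.37), HK2 (0.64 ± 0.13), ASNS (0.56 ± 0.18) and LDHA (0.47 ± 0.10). Called lower in the Nutlin-3 interaction were MT1G (-7.01 ± 1.14), RGPD1 (-5.78 ± 1.71), GOLGA8R (-5.32 ± 1.79), FAM229A (-5.08 ± 0.44), LHX4-AS1 (-5.06 ± 0.36), MT1F (-4.71 ± 0.81), NLRP1 (-4.67 ± 0.43), OTUD6B-AS1 (-4.57 ± 0.40), TXNIP (-1.63 ± 0.24) and PARP1 (-0.49 ± 0.08). No change was called in the Nutlin-3 interaction for VEGFA (0.11 ± 0.16), CA9 (2.021 ± 1.00), ATF4 (-0.03 ± 0.11) and BBC3 (-0.02 ± 0.27), but CA9 was called without B87+DMKG replicate 2 (2.39), Control replicate 2 (2.44) or Nutlin-3 replicate 3 (2.61, adjusted p = 0.0374). Other genes of the naming rule that were higher in the Rita interaction were MTRNR2L8 (3.89 ± 0.72), LINC01433 (3.16 ± 0.96), IL1A (2.95 ± 0.36), BARX1 (2.94 ± 0.88), TRIB3 (2.86 ± 0.24), DDIT3 (1.499 ± 0.35), ASNS (1.46 ± 0.17), GDF15 (1.18 ± 0.26), SLC2A1 (1.05 ± 0.14), VEGFA (0.99 ± 0.16), BBC3 (0.92 ± 0.26), ATF4 (0.91 ± 0.10), LDHA (0.37 ± 0.10), HK2 (0.33 ± 0.13) and PARP1 (0.23 ± 0.08). Those lower in the Rita interaction were MT1G (-7.29 ± 1.09), RGPD1 (-7.13 ± 1.64), GOLGA8R (-5.70 ± 1.72), GOLGA8A (-5.06 ± 0.63), ASMTL-AS1 (-4.73 ± 1.006), MT1F (-4.29 ± 0.78) and TXNIP (-1.69 ± 0.23). Not past the test in the Rita interaction was CA9 (0.80 ± 0.96). In the Rita interaction the calls of HK2 (0.239, adjusted p = 0.139), LDHA (0.118, 0.329) and PARP1 (0.184, 0.0801) were lost with quantile normalization, and those of HK2 (0.262, 0.128) and PARP1 (0.168, 0.108) with the same total. That of HK2 was also lost with no filter on low values (0.0658) and without B87+DMKG replicates 2 (0.29, adjusted p = 0.0729) or 3, B87+DMKG+Rita replicates 1 or 3, Control replicates 1 or 4, or Rita replicate 3 (0.29, 0.0752).

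Against Control, B87+DMKG+Nutlin-3 changed 9434 rows (4602 up, 4832 down; 2867 by at least 1, 869 up and 1998 down) and B87+DMKG+Rita 9767 (4774 up, 4993 down; 3177 by at least 1, 1239 up and 1938 down). With Nutlin-3, EGR1 (5.73 ± 0.20), KLF2, a shear-responsive transcription factor (4.43 ± 0.29), GDF15 (4.38 ± 0.18) and JUN (3.71 ± 0.11) were among the largest rises, and CUL3 (-5.97 ± 0.10), NANOS1 (-4.63 ± 0.55), ADGRA3 (-4.36 ± 0.12), TIMM21 (-3.99 ± 0.11) and SBNO1 (-3.98 ± 0.13) among the largest falls. PARP1, the DNA damage-sensing polymerase, was lower (-1.11 ± 0.06), and no list was called with an estimated correlation (p53 targets 16 of 29 up and 5 down, 16 and 5 adjusted over the list alone, adjusted p = 0.072). With Rita, FAM71A (9.02 ± 0.41), FOSB (6.64 ± 0.30), EGR1 (5.60 ± 0.20) and ATF3 (4.66 ± 0.25) were among the largest rises, and MAML3 (-4.47 ± 0.16), RGL1 (-4.41 ± 0.46), MEIS1 (-3.90 ± 0.29) and TET1, a DNA demethylase that uses α-ketoglutarate (-3.65 ± 0.37), among the largest falls. Of 18 immediate early genes 17 were up and 1 down (17 and 1 adjusted over the list alone; camera adjusted p = 0.011 with an estimated correlation). Of 29 p53 targets 16 were up and 3 down (16 and 3 adjusted over the list alone; adjusted p = 0.015 with an estimated correlation), but with the same total 11 were up and 6 down, and the median went from 0.348 to 0.0912. Of 16 endoplasmic reticulum genes 12 were up and 1 down (12 and 1 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation), and their median went from 0.524 to 0.267 with the same total. Scaled to the same total, 33.8% of the calls were up against 48.8% with Nutlin-3 (55.7% under quantile normalization) and 27.9% against 48.9% with Rita. The naming rule also gave FOS (3.97 ± 0.20), DDIT4 (3.58 ± 0.12), FOSB (3.58 ± 0.30), SPDYE8P (3.53 ± 0.26), CDKN1A (3.39 ± 0.10), BBC3 (2.26 ± 0.18), DDIT3 (1.94 ± 0.25), MDM2 (1.15 ± 0.09), TRIB3 (1.13 ± 0.17), SLC2A1 (0.44 ± 0.10), HK2 (0.38 ± 0.09) and LDHA (0.35 ± 0.07) as higher with Nutlin-3. Genes lower with Nutlin-3 were ST20-AS1 (-5.54 ± 0.58), SPRY3 (-5.47 ± 1.82), SKIDA1 (-3.98 ± 0.21), TXNIP (-0.45 ± 0.16) and ATF4 (-0.19 ± 0.07). The test was not passed with Nutlin-3 by VEGFA (-0.15 ± 0.11), CA9 (1.28 ± 0.68) and ASNS (-0.07 ± 0.12). Without Control replicate 3, ASNS (-0.239, adjusted p = 0.0492) and VEGFA (-0.302, 0.0113) were called lower, VEGFA also with the same total (-0.315, 0.0131). With Nutlin-3 the calls of LDHA (0.06, adjusted p = 0.473) and TXNIP (-0.198, 0.304) were lost with quantile normalization, that of HK2 with the same total in every library (0.223, 0.0587), that of ATF4 without Control replicates 1, 2 (-0.12, 0.162) or 4, without B87+DMKG+Nutlin-3 replicates 2 or 4 or with no filter on low values (0.0745), that of TXNIP also without Control replicates 1 (-0.331, 0.0984), 2 or 4 or without B87+DMKG+Nutlin-3 replicate 3, and that of SPRY3 with DESeq2 (-2.95, 0.356) and edgeR (-2.93, 0.0634). Also higher with Rita were C1orf116 (6.05 ± 0.49), MTRNR2L9 (5.15 ± 1.64), C11orf96 (4.95 ± 0.64), FOS (4.75 ± 0.20), GDF15 (3.74 ± 0.18), CDKN1A (2.91 ± 0.10), DDIT3 (2.59 ± 0.25), BBC3 (2.37 ± 0.18), ASNS (1.33 ± 0.12), TRIB3 (0.95 ± 0.17), VEGFA (0.90 ± 0.11), ATF4 (0.67 ± 0.07), LDHA (0.25 ± 0.07) and MDM2 (0.24 ± 0.09). Called lower with Rita were SPRY3 (-5.46 ± 1.82), MAML2 (-4.17 ± 0.26), PDE7B (-3.70 ± 0.17), GLI2 (-3.68 ± 0.18), TXNIP (-0.92 ± 0.16) and SLC2A1 (-0.68 ± 0.10). No change was called with Rita for HK2 (0.06 ± 0.09), CA9 (1.12 ± 0.68) and PARP1 (-0.08 ± 0.06), but PARP1 was called lower with quantile normalization (-0.295) and the same total (-0.34, adjusted p = 1.6e-05). With Rita the directions of MDM2 (-0.015, adjusted p = 0.904) and LDHA (-0.004, 0.962) turned with the same total in every library. With quantile normalization LDHA turned (-0.064, 0.438) and MDM2 lost its call (0.09, 0.4). The calls of SPRY3 (-2.9, 0.359) and MTRNR2L9 (3.59, 0.119) were lost with DESeq2, that of SPRY3 also with edgeR (-2.87, 0.0658). That of MDM2 was lost without B87+DMKG+Rita replicate 3 (0.215, 0.0522) or Control replicate 2 (0.208, 0.0574).

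The triple treatments differed from each other in 7856 rows (3875 up, 3981 down; 2806 by at least 1, 1202 up and 1604 down). Up calls were 49.3% of all, 54.8% under quantile normalization and 58.9% scaled to the same total. RGL1 (4.72 ± 0.46), MAML2 (4.42 ± 0.26), MAML3 (3.76 ± 0.16), KLF2 (3.63 ± 0.29) and TET1 (3.46 ± 0.37) were higher with Nutlin-3, and FAM71A (-9.02 ± 0.41), NANOS1 (-4.99 ± 0.55), NHLH1 (-4.67 ± 0.24), the Notch-regulated gene NRARP (-4.52 ± 0.14), CUL3 (-4.27 ± 0.10) and PMAIP1 (-2.91 ± 0.15) were higher with Rita. Of 23 integrated stress response genes 18 were higher with Rita (18 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation), such as ASNS (-1.40 ± 0.12). Conversely, 15 of 21 mitosis genes were higher and 1 lower with Nutlin-3 (15 and 1 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation), such as AURKA (1.12 ± 0.06). CDKN1A (0.48 ± 0.10) and MDM2 (0.90 ± 0.09) were higher with Nutlin-3. BBC3 (-0.11 ± 0.18) did not pass the test. Other genes of the naming rule that were higher with Nutlin-3 were RGPD1 (4.21 ± 1.16), ZNF804A (3.61 ± 0.13), ZBTB20 (3.28 ± 0.39), SLC2A1 (1.12 ± 0.10), GDF15 (0.64 ± 0.18), TXNIP (0.47 ± 0.16) and HK2 (0.32 ± 0.09). Those higher with Rita were ST20-AS1 (-5.15 ± 0.58), HIC1 (-5.09 ± 0.69), FAM43A (-4.13 ± 0.26), VEGFA (-1.05 ± 0.11), PARP1 (-1.02 ± 0.06), ATF4 (-0.86 ± 0.07) and DDIT3 (-0.65 ± 0.25). Not past the test were LDHA (0.09 ± 0.07; called with the same total at 0.189, adjusted p = 0.00866), CA9 (0.16 ± 0.68) and TRIB3 (0.18 ± 0.17). The call of DDIT3 was lost when single libraries were left out (-0.617, adjusted p = 0.0695 without B87+DMKG+Rita replicate 3), as it was without its replicates 1 or 4 and without B87+DMKG+Nutlin-3 replicates 1, 2 or 4. It was lost too with the same total in every library (-0.552, 0.0652) and with no filter on low values (0.0659).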

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

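The tests of outlying libraries here were planned, and the tests of other groupings of the libraries were too; the genes tested for an outlying library were chosen only after the results were seen. Among 77 groups of values, 5 held an outlying library by Dixon's ratio, and chance gives about 1 in 20 groups. CHAC1 was low in Control replicate 3 (ratio 0.9038; 710 against 3113 to 3369 in the other Control libraries), so its fall in B87+DMKG is measured from an uneven Control. HK2 was low in B87 replicate 4, the library with the fewest reads (0.8662), TXNIP was high in DMKG replicate 2 (0.9083), and Rita replicate 4 was high in both EGR1 (0.8406) and the share of reads on the mitochondrial genome (0.886). The effect of a treatment depended on the others present for many genes: 7927 for the combination against the sum of its parts, 9259 for Nutlin-3 and 7897 for Rita with against without B87+DMKG.

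Other groupings of the same libraries were run for each count, and the real grouping is included in the number as large. Of 35 groupings, only the real one (1) gave as many calls for B87+DMKG (9922, highest other 3252), DMKG (6725, 1076), Nutlin-3 (6359, 3865), Rita (8468, 1358), adding Nutlin-3 (9570, 3805), adding Rita (10937, 3510), and the triple treatments against Control (9434, 3860 with Nutlin-3, and 9767, 1 with Rita) and each other (7856, 126). That is the smallest number 35 groupings can give, and it was not adjusted for the number of comparisons. Nor can such groupings tell a treatment from a technical difference between groups. For B87, 2 of 35 gave as many (7, highest other 10), so chance is not excluded. Of 100 groupings for the 4-group contrasts, 1 gave as many for the combination beyond additive (7927, highest other 6247), the Nutlin-3 interaction (9259, 4651) and the Rita interaction (7897, 7760), and for reversal 1 by Nutlin-3 (4960, 2108) and 2 by Rita (6011, 7126). For gene lists 4 of 100 gave as many calls at the preset correlation (105, highest other 110), and with the correlation estimated 1 did (22, highest other 3). Under 1 in 20 groupings gave as many in each of these. These groupings shuffled the libraries of all groups involved, which stands for no difference between any groups. They therefore cannot tell whether an interaction or a reversal by itself exceeds chance. The median of the other groupings was 0, except for the lists at the preset correlation (77), where 3 others gave as many as the real one. A list call at the preset correlation alone therefore carries little weight. The margin is small for the Rita interaction, and for reversal by Rita 1 other grouping exceeded the real one.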

How the results depend on the processing

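The DMKG libraries left out in pairs and the rows that name 1 gene were chosen only after seeing the data. At an absolute log2 fold change of at least 1, counts fell to 3391 (B87+DMKG), 1 (B87), 1691 (DMKG), 3217 (beyond additive), 1223 (Nutlin-3), 2272 (Rita), 2973 and 4286 (adding Nutlin-3 and Rita), 4456 and 3124 (their interactions), 2867 and 3177 (triples against Control) and 2806 (triples compared), which follows from the threshold. B87 went from 7 to 14 with only its groups, 30 with DESeq2 and 2 to 7 without 1 library (2 without B87 replicate 4). With the replicate number as a block, B87 gave 9 and B87+DMKG 9808, and numbers did not pair libraries (mean correlation -0.008). List calls went from 105 to 22 with the correlation estimated. Reversal ranged from 43.6% to 51.8% (Nutlin-3) and 55% to 62.3% (Rita). Without DMKG 3 and 4, DMKG gave 5023, without 1 and 2 6816. Directions turned for LDHA in B87+DMKG+Rita vs Control (-0.064 with quantile normalization, -0.004 with the same total) and Rita (-0.144, same total), PARP1 on adding Rita (-0.047, same total), MDM2 in B87+DMKG+Rita vs Control (-0.015, same total), and NRF2 targets on adding Rita (camera adjusted p 0.6973, quantile). B87 replicate 4 had the fewest reads. The cause was not tested where values moved.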

Other observations

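The families here were tested only after the results were seen, as were the tests of MALAT1, of gene span and of libraries shared by the steps below. Zinc finger genes named ZNF fell with DMKG: of 395 tested, 195 fell and 46 rose, with a median of -0.42 (camera adjusted p = 0.0113 with an estimated correlation). Against the sum of B87 and DMKG, 14 of 27 HOX genes, which pattern the body axis and are silenced by chromatin marks, were higher and 0 lower (adjusted p = 0.0387 with an estimated correlation), 119 of 346 antisense genes were higher and 16 lower (0.0109), and 56 of 152 LINC genes were higher and 7 lower (0.00864). With DMKG alone 16 HOX, 83 antisense and 46 LINC genes fell and 4, 32 and 10 rose, families not called there (0.0901, 0.261 and 0.141). Nor were they called in B87+DMKG against Control, with 11 HOX genes up and 10 down (0.747), 120 and 42 antisense (0.119) and 50 and 24 LINC (0.173). Rows without a symbol were higher than the sum of B87 and DMKG in 898 and lower in 169 of 2416 cases (0.0118). Against Control 1071 rose and 299 fell with B87+DMKG, again not called (0.0537). Leaving out those on the mitochondrial genome, they held 1.03% ± 0.0151 of the reads in B87+DMKG against 0.828% ± 0.00863 in Control (SD, n = 4 each). On adding Nutlin-3 the 2416 rows without a symbol fell in 1189 and rose in 213 cases (0.0381), and on adding Rita they fell in 1130 and rose in 392, which was not called (0.161). In the Rita interaction 915 were lower and 183 higher (0.022). The Nutlin-3 interaction, with 1079 lower and 211 higher, was not called (0.0595).

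Most movement on adding Nutlin-3 or Rita ran against the B87+DMKG change. The libraries shared by both steps do not account for it, since with these split there were still at least 1.76313 (Nutlin-3) and 2.66173 (Rita) opposite calls for each call in the same direction. This test replaced one against simulated unchanged groups, which could not fail because such groups have almost no calls. The inhibitor alone made the same call in 7.66% (Nutlin-3) and 24.0% (Rita) of the genes that moved back. These genes were chosen against the same Control libraries, which lowers this share, and the Control libraries were not split for it. A missing call is also not an absent effect, so these calls do not settle how much its own effect covers. An interaction was called in the direction of the move back in 84.1532% and 83.6966% of these genes, against 56.9% and 48.6% of all rows in either direction. The interaction contains the change by which these genes were chosen, so its share does not decide the question. The interaction shares the B87+DMKG and Control libraries with the change it is set against, and a weaker B87+DMKG stimulus in the cell, a chemical interaction in the medium, a difference in cell number surviving at 6 h and a limit on how far a gene can move stay open as untested.

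Genes with longer spans fell more with Rita, in whose libraries the 45S rRNA share was also higher. For Rita alone, annotated exonic length does not account for all of it. It was taken for the transcript length that RNA breakage would follow in poly(A) libraries. The correlation was -0.512, and -0.397838 at fixed exonic length. On adding Rita to B87+DMKG it went from -0.306 to -0.192, and for B87+DMKG+Rita vs Control from -0.428 to -0.274. A part may thus follow exonic length. That length joins all annotated exons of a gene and can differ from the transcript made in these cells. A larger part from transcript length or RNA quality is therefore not excluded. Low expression of long genes does not account for the pattern with Rita alone (-0.520086 in the third of genes with the highest mean). Slower transcription along genes and differences in RNA stability stay open, since neither new transcripts nor RNA decay was measured.

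MALAT1 was higher in B87+DMKG than in Control. Library depth does not account for it, since both groups had similar reads (means 52.2 M in B87+DMKG and 50.0 M in Control). Thinning to equal depth could therefore hardly have removed the difference. After it the lowest B87+DMKG library stood 3.85246 above the Control mean on the log2 scale. A larger share of nuclear RNA would raise other nuclear-retained RNAs, and 11 of them had a median of 0.529056 (SD 0.78), against 4.08 for MALAT1. Most of the 11, such as CCNL1 and CLK4, also code for proteins. Their rows can count cytoplasmic messenger RNA too, so they need not rise alike. The non-coding KCNQ1OT1 (2.27), NEAT1 (0.36) and TUG1 (0.30, not called) also changed less than MALAT1. Of the 11, 7 were called up and 1 down, so a part from this source is not excluded. The share of reads of MALAT1 in Control was low for this gene, so the row may hold only part of its reads, and how they were assigned stays open.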
